A study of Homo sapiens with 12 samples.

How the data were processed

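RNA from A375 and SK-MEL-28 cells, treated with XL413 or DMSO, was sequenced in 12 libraries, 3 for each line and treatment. The groups were taken from the sample titles. The labels give the doses and times as 1 µM for 24 h in the sample descriptions and 10 µM for 48 h in the treatment protocol, and the difference could not be settled from the data. The extraction notes describe selection with oligo-dT beads and strand-specific libraries, while the series design describes depletion of ribosomal RNA and random priming. In oligo-dT libraries RNAs without a poly(A) tail are captured poorly, and in depleted libraries they are retained, so values of histones and small RNAs depend on which applied.

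The authors' notes name Trimmomatic 0.33, HISAT2 2.1.0 and StringTie 1.3.3b, and the hg38 genome. The deposited table holds one value per gene and library and does not name its unit. The values were taken as FPKM (fragments scaled by transcript length and library size, as StringTie writes them) because the deposited sums per library, from 423940 to 520281, differ and are not those of TPM. Low values of 12431 genes with 1 exon and 1 transcript also cluster at multiples of one step per library, within 3% of a whole read for 36.4% to 40.6% of the values examined. That step was used to infer the depth, from 25.9 to 47.2 M fragments, so that 1 fragment per kilobase equals 0.0212 to 0.0386 FPKM. The share of values on whole reads was too low to recover counts, so count models such as DESeq2 were not used. No interval from counting error could be given. FPKM divides by transcript length, so a change in which part of long transcripts is captured alters long and short genes differently.

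The table has 58247 entries and 58243 gene IDs. Gene names come from the table, and coordinates, types, lengths and GC content from GENCODE release 29, whose locus was equal for 97.1% of entries. The 37 genes of the mitochondrial chromosome are listed at 0 in every library, and single genes jump between 0 and a high level, so a 0 in this table was not read as absence. Genes at 0 in a whole group are given as values per library, without a fold.

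Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept (16205). Values were put on a log2 scale after adding 0.1. One linear model with 4 group means and 8 residual degrees of freedom was fitted with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend), so all libraries share in the estimate of the spread. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg, with 0.05 as the threshold. The contrasts were XL413 against DMSO in A375, the same in SK-MEL-28, and the difference between these (SK-MEL-28 minus A375). Fold changes are on the log2 scale, and FPKM are means with SD. Where a fold change and a p stand together in parentheses, the p is adjusted.

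Before the data were examined, 30 gene lists (733 entries) were fixed, of which 26 had at least 5 tested genes. They cover replication, the cell cycle, DNA damage, cell death, inflammation, stress, melanocyte states, signalling, metabolism, ribosomes and markers of other cell types. They were tested with camera (preset correlation of 0.01, beside an estimated correlation) and fry, adjusted over the lists. The members of a list were also adjusted over that list alone, which changed the counts in SK-MEL-28 by at most 2 in either direction. The 13 mitochondrially encoded mRNAs on one list had no value above 0.

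Named genes were chosen by a rule fixed at the same time. It takes CDC7, DBF4, up to 8 of the largest rises and falls per line among called genes with no overlap between groups and a mean of at least 5 FPKM in the higher group, and up to 4 members of each list. It also takes the largest differences between the lines and up to 5 genes called in both lines in each direction or in opposite directions. Fewer were named where the text grew long, always from the top. Results for a few genes on the lists or in this rule, and for lists that need them, are not reported here. Where 5 or fewer members of a list moved one way they are named without values, a choice made after their values were seen.

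The code was tested on simulated libraries, built from the fitted group means and independent random noise of the fitted spread, with changes planted in few genes. Of planted 1.5-fold changes it recovered 25.4% in A375 and 34.3% in SK-MEL-28, of 2-fold changes 73.1% and 62.7%, and of 4-fold changes 90.9% and 89.4%, with 6.7% and 2.4% of calls false. A planted list was called in both lines, with 0 and 1 of the 26 lists called by mistake. The simulated noise had no correlation among genes and no trend with length or GC content. These rates therefore need not hold in the real libraries.

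Alternatives were a pseudocount of 1 or 0.01, no filter or a mean of at least 5 FPKM, the median of ratios or quantile normalization, the replicate number as a block, each line fitted alone, robust eBayes, weights per library, a 2-fold minimum, and leaving out each library in turn. Added after the data were seen were protein-coding genes alone, a correction of each library for its trend with transcript length and GC content (splines with 5 degrees of freedom, on protein-coding genes), the removal of genes ranging over 8-fold within a group, and quantile normalization for the lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.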

Results

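Gene expression was measured by RNA sequencing in 12 libraries from A375 and SK-MEL-28, a pair of established human melanoma lines. The cells had received XL413, a small-molecule inhibitor of the kinase CDC7, or DMSO, the solvent used as its control. CDC7, with its activator DBF4, phosphorylates the MCM helicase to start DNA replication. Each line had 3 DMSO and 3 XL413 libraries, which the series describes as biological replicates. The sources used here give no read totals. The steps between low values of single-exon genes implied a depth of 39.6, 42.7 and 43.7 M fragments (M, mega) in the A375 DMSO replicates 1, 2 and 3, and of 25.9, 26.7 and 45.2 M in the A375 XL413 replicates. For SK-MEL-28 the implied depth was 47.2, 42.5 and 31.7 M fragments with DMSO and 33.1, 27.5 and 39.4 M with XL413. The labels differ on the treatment: the sample descriptions give 1 µM for 24 h, whereas the treatment protocol gives 10 µM for 48 h. They differ on the libraries too, naming oligo-dT beads in the extraction notes and depletion of ribosomal RNA in the series design. Across the 16205 genes tested, the lines separated on the first principal component, which held 81.3% of the variance, and replicates of a group correlated with Pearson's r from 0.965 to 0.976 on the log2 scale.

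The A375 comparison asked which transcripts change in this line when CDC7 is inhibited. Genes of G2 and mitosis rose together: of the 30 on this list, 18 rose and 0 fell by limma (23 at an unadjusted p under 0.05). Adjusted over the list alone 22 rose, and the median log2 fold change was 0.45. CDK1, the kinase that drives entry into mitosis, went from 56.1 ± 0.235 to 105 ± 8.46 FPKM (mean ± SD, n = 3 here and below). TOP2A, the topoisomerase that untangles chromosomes, went from 106 ± 3.86 to 195 ± 15.3 FPKM. UBE2C, which helps mark mitotic proteins for destruction, went from 88.7 ± 3.5 to 160.2 ± 12.6 FPKM, and HMMR, a protein of the mitotic spindle, from 42.8 ± 1.14 to 76.5 ± 2.60 FPKM. These 4 rises were 0.89, 0.88, 0.85 and 0.84 on the log2 scale, with an adjusted p = 0.00119 or lower, and in each the 3 XL413 libraries lay above the 3 DMSO libraries. The list stood above the other genes by camera (adjusted p = 6e-28), also when the correlation among its genes was estimated (adjusted p = 0.0014). CDK1 (ENSG00000170312) lies on chromosome 10, from 60778331 to 60794852 on the plus strand of hg38, and TOP2A (ENSG00000131747) on chromosome 17, from 40388516 to 40417950 on the minus strand.

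**Figure D1:**
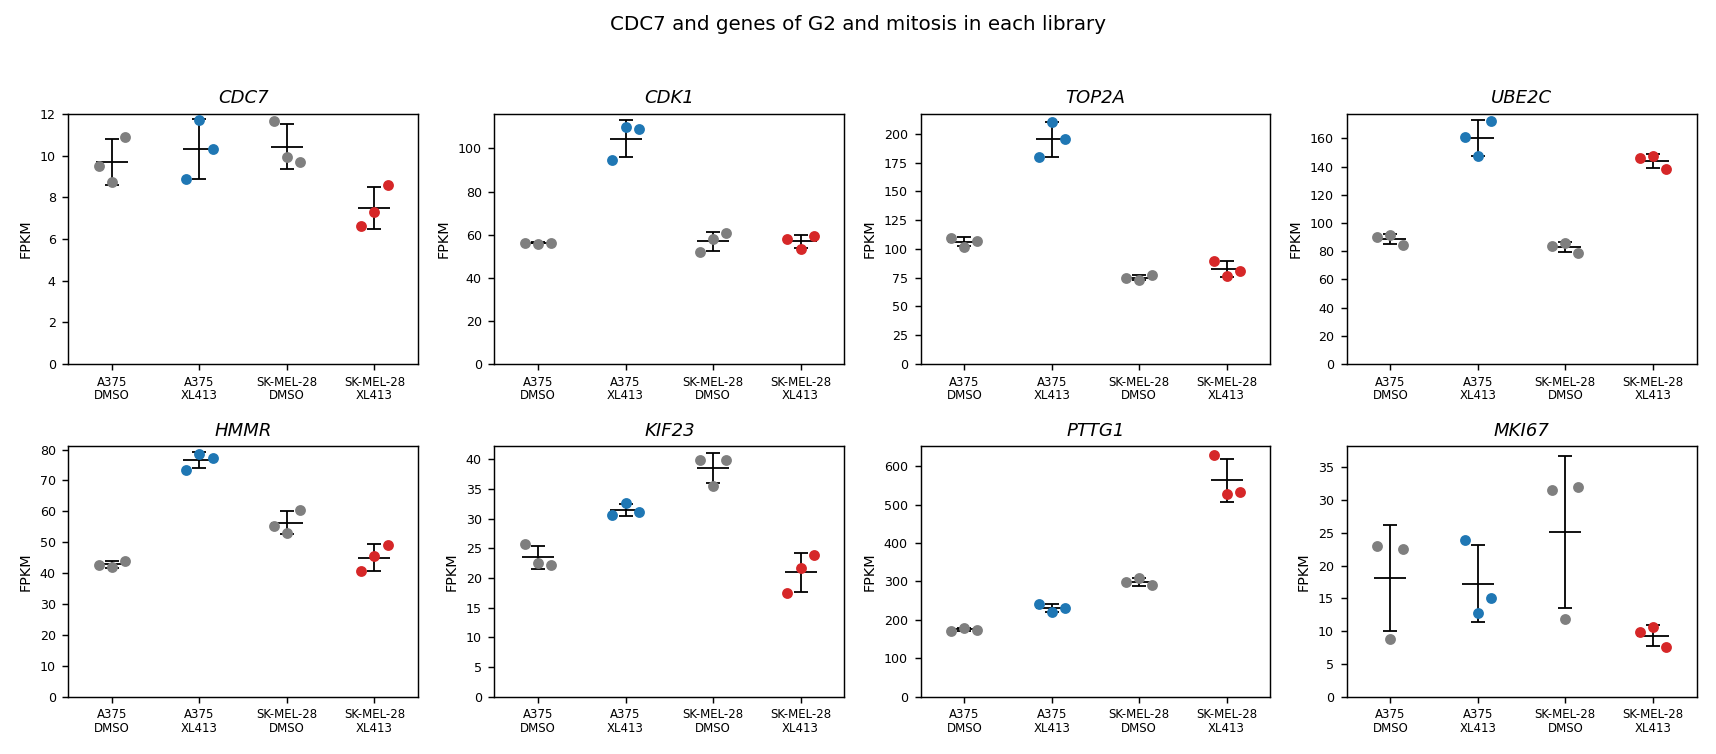
FPKM (vertical axes, from 0) of CDC7 and 7 genes of G2 and mitosis in each library, by cell line and treatment; points are libraries, and bars are the mean and SD of 3. CDK1, TOP2A, UBE2C and HMMR sit higher in every A375 library with XL413 than in any with DMSO, while in SK-MEL-28 UBE2C and PTTG1 sit higher and KIF23 lower.

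The target of the drug showed no detectable change in its own transcript in A375: CDC7 (ENSG00000097046; chromosome 1, from 91500893 to 91525764) was at 9.70 ± 1.09 FPKM with DMSO and 10.3 ± 1.43 FPKM with XL413 (log2 fold change 0.08, adjusted p = 0.818). DBF4 was at 9.12 ± 2.07 and 11 ± 2.89 FPKM (adjusted p = 0.67). Among the 30 proteins that license and fire replication origins, CDC45 and MCM5, both parts of the replicative helicase, fell by 0.46 and 0.33 on the log2 scale. Adjusted over this list alone, 3 fell and 1 rose (camera adjusted p = 0.79). CCNE2, a cyclin of S phase entry, fell by 0.60 and was the only one of 30 DNA synthesis and E2F targets called (3 lower when adjusted over the list alone). BAX, a promoter of apoptosis, was not called, with a log2 fold change of -0.68 (adjusted p = 0.0843; -0.90 and called without DMSO replicate 3, adjusted p = 0.031). The 9 replication-dependent histone genes tested had a median of 0.40 with none called, 2 at an unadjusted p under 0.05 and a camera adjusted p = 0.053. Without the filter on low values, 9 of 18 table entries of such genes had a higher mean and 9 a lower one (median 0.03, untested). HIST1H4C was at 1.51 (adjusted p = 0.0713). Camera called this list under quantile normalization (median 0.52, adjusted p = 0.0085) and after the correction for length and GC content (0.38, 0.014), but not with an estimated correlation (adjusted p = 0.61 and 0.45).

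Single members of other lists changed in A375. BIRC2, an inhibitor of apoptosis, rose by 0.26 on the log2 scale (1 of 29 apoptosis regulators). CXCL8, a chemokine, rose by 0.37 (1 of 25 NF-kB and secreted inflammatory factors), P4HA1, which hydroxylates collagen, by 0.29 (1 of 25 hypoxia and glycolysis genes), and SPARC, a secreted matrix protein, by 0.49 (1 of 26 extracellular matrix and adhesion genes). ISG15, a ubiquitin-like interferon-induced protein, fell by 0.79 (1 of 25 interferon response genes) and JUND, an AP-1 transcription factor, by 0.50 (1 of 24 immediate early genes). Of 30 unfolded protein and ATF4 stress response genes, SDF2L1 fell by 0.47 and CEBPB by 0.31. By camera none of these lists stood apart (adjusted p = 0.34 or higher). In the same comparison the log2 fold change fell with GC content across 12156 protein-coding genes (Spearman's rho -0.43). Correcting each library for length and GC content ended the calls of these 8 genes, at 0.12 for BIRC2, 0.24 for CXCL8, 0.17 for P4HA1, 0.42 for SPARC, -0.56 for ISG15, -0.18 for JUND, -0.22 for SDF2L1 and -0.07 for CEBPB (adjusted p 0.086 to 0.62). In 16 of the 26 lists large enough to test, limma called no member. Beside the histones, these included DNA damage repair, melanocyte differentiation, the invasive melanoma state, MAPK output, cholesterol synthesis, NRF2 response, aryl hydrocarbon receptor response, lysosome and autophagy, TGF-beta and YAP targets, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, antigen presentation and fibroblast markers. Of their 328 tested genes, 54 (16.5%) had an unadjusted p under 0.05, a share similar to that of all tested genes (2811 of 16205).

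The largest single rises in A375 included MEX3C, an RNA-binding ubiquitin ligase (ENSG00000176624; chromosome 18, from 51174550 to 51218304), which went from 8.69 ± 0.573 to 23.1 ± 1.28 FPKM (log2 fold change 1.40, adjusted p = 0.00099), and SPIN1, a reader of histone methylation, which rose by 1.02. LRMDA, linked to melanocyte differentiation, rose by 1.10, LSM5, a part of the U6 RNA complex, by 1.03, and PYROXD1, an oxidoreductase, by 0.95. EMILIN2, an extracellular matrix glycoprotein (ENSG00000132205; chromosome 18, from 2847030 to 2915993), fell from 7.22 ± 0.278 to 2.53 ± 0.249 FPKM (log2 fold change -1.48, adjusted p = 0.00019). ATG16L2, a relative of an autophagy factor, fell by 1.22, FAM173A, a methyltransferase, by 1.15, DBNL, an actin-binding protein, by 1.07, and CSAD, an enzyme of taurine synthesis, by 1.04. CT45A3, one of a family of near-identical cancer/testis genes on chromosome X, was listed at 0 in the 3 DMSO libraries and at 28.8, 25 and 27.5 FPKM with XL413. The 9 CT45A genes together summed to 74.9, 116.1 and 117.5 FPKM with DMSO and to 128.4, 144.2 and 135 FPKM with XL413.

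In A375, 258 of 16205 genes passed the threshold (97 higher, 161 lower; 2811 at an unadjusted p under 0.05), 28 of them with at least a 2-fold change (8 higher, 20 lower), and the treated and control libraries did not overlap for 28.4% of genes, where chance gives 10%. With libraries rescaled by their median of ratios, the split was 56.8% higher in place of 37.6%. The count fell to 43, 48 or 49 without DMSO replicate 1, 2 or 3 and to 67 or 88 without XL413 replicate 2 or 3. It fell to 96, 100 or 159 without SK-MEL-28 DMSO replicate 1, 2 or 3 and to 128 or 130 without SK-MEL-28 XL413 replicate 2 or 3, since all libraries share in the estimate of the spread. CDC45, MCM5, CCNE2, BIRC2, CXCL8, P4HA1, SPARC, ISG15, JUND, SDF2L1, CEBPB, LRMDA, LSM5, PYROXD1, DBNL and CSAD lost their calls without DMSO replicate 1 (adjusted p 0.05 to 0.14), and most of them without DMSO replicate 2 or 3 or XL413 replicate 2 or 3 as well (up to 0.17), each in an unchanged direction. DBNL, ISG15, CCNE2, CSAD and SPARC did so without XL413 replicate 1 (0.053 to 0.074), and DBNL, CDC45, ISG15, SDF2L1 and CEBPB after rescaling by the median of ratios (0.054 to 0.068). The correction for length and GC content also ended the calls of CDC45, PYROXD1, DBNL and CSAD (0.052 to 0.11), although their fold changes stayed close, at -0.44, 0.79, -0.95 and -1.04.

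In SK-MEL-28 the same question gave a far wider change, which included single genes of the melanocyte lineage, of the cell surface and of DNA repair. MITF, the transcription factor that governs melanocyte identity (ENSG00000187098; chromosome 3, from 69739435 to 69968337), fell from 150.2 ± 9.25 to 33.7 ± 2.37 FPKM (log2 fold change -2.15, adjusted p = 3.3e-06). ITGB3, an integrin subunit, fell from 64.3 ± 4.46 to 19.4 ± 3.5 FPKM (-1.74, adjusted p = 2.03e-05), and TNC, a matrix glycoprotein of invasive cells, from 355 ± 84.0 to 115 ± 35.5 FPKM (-1.64, adjusted p = 0.000333). ATM, the kinase that signals DNA breaks, fell from 35.2 ± 7.76 to 7.98 ± 1.69 FPKM (-2.13, adjusted p = 0.000255). In each, the 3 XL413 libraries lay below the 3 DMSO libraries.

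Of 26 extracellular matrix and adhesion genes, 14 fell and 1, TIMP1, rose (13 and 2 after rescaling by the median of ratios), with COL4A2, a basement membrane collagen, at -1.61. Adjusted over the list alone, 15 fell and 2 rose. By camera the list fell (median -0.40, adjusted p = 0.0068), but not with an estimated correlation (adjusted p = 0.28). The invasive melanoma state lost 9 of 21 genes and gained none by limma (11 at an unadjusted p under 0.05; camera adjusted p = 0.2), although quantile normalization left 3 lower and 2 higher (0.61). Of 24 melanocyte differentiation genes, 6 fell and BCL2A1, a survival factor driven by MITF, rose by 0.63, against 4 lower and 3 higher by the median of ratios. GPNMB, a melanosome protein, fell by 0.70 and SOX10, which acts upstream of MITF, by 1.2 (camera adjusted p = 0.55). Under quantile normalization camera called the melanocyte list lower (median -0.37, adjusted p = 0.0019), but not with an estimated correlation (adjusted p = 0.13). The fall in SOX10 was not called by the median of ratios (adjusted p = 0.057), nor without DMSO replicate 2 (log2 fold change -0.66, adjusted p = 0.069), XL413 replicate 2 (-1.08, 0.096) or XL413 replicate 3 (-1.09, 0.095). The median transcript was 5400 nt long for the matrix list, 4332 nt for the invasive list and 2801 nt for the melanocyte list, beside 3062 nt over all tested protein-coding genes.

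**Figure D2:**
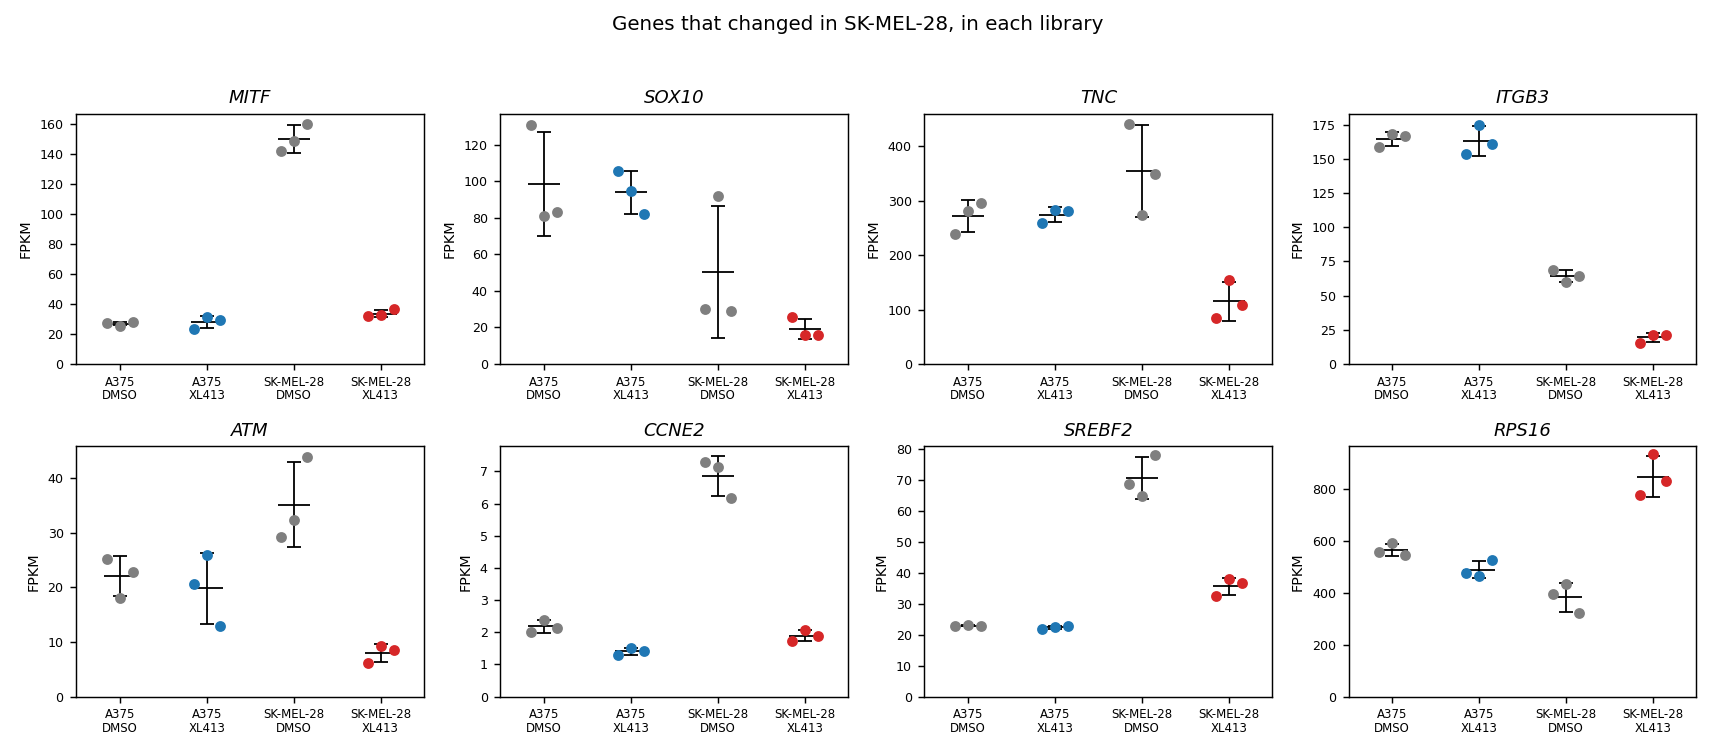
FPKM (vertical axes, from 0) of 8 genes that changed in SK-MEL-28, in each library, by cell line and treatment; points are libraries, and bars are the mean and SD of 3. MITF, SOX10, TNC, ITGB3, ATM, CCNE2 and SREBF2 sit lower and RPS16 higher in every SK-MEL-28 library with XL413 than in any with DMSO. For SOX10, DMSO replicate 2 lies far above the other SK-MEL-28 libraries.

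Genes of DNA replication and repair fell in SK-MEL-28 more often than they rose, as did protein-coding genes in general. Of 12188 protein-coding genes in the same test, 3953 fell and 1584 rose. Of 30 proteins that license and fire origins, 13 fell and 1 rose (10 and 3 by median of ratios). DBF4B, a relative of DBF4, fell by 1.21, MCM2, a helicase subunit, by 1.02 and TOPBP1, which activates ATR, by 0.94, while RECQL4, a helicase of origin firing, rose by 0.63 (camera adjusted p = 0.14). CDC7 fell from 10.4 ± 1.06 to 7.5 ± 0.997 FPKM (log2 fold change -0.47, adjusted p = 0.018), a call lost after rescaling (adjusted p = 0.054), without DMSO replicate 1 (0.068) and without XL413 replicate 1 (0.066). DBF4 was at 8.33 ± 1.53 and 6.02 ± 1.47 FPKM (adjusted p = 0.168). Of 30 DNA synthesis and E2F targets, 14 fell and 1, RNASEH2A, rose (9 and 4 by median of ratios). CCNE2 fell by 1.81, RRM2, which makes deoxynucleotides, by 0.90, and the polymerase subunits POLD3 and POLA1 by 0.84 and 0.83 (camera adjusted p = 0.18). Of 29 DNA damage repair and checkpoint genes, 16 fell, with BRCA2 and XRCC2, both of homologous recombination, each at -1.34, and RBBP8, CHEK2 and RPA2 rose (camera adjusted p = 0.12; 18 lower and 3 higher when adjusted over the list alone). By the median of ratios 10 fell and 3 rose, and the correction for length and GC content left 11 lower and 2 higher and moved this list's median from -0.47 to -0.21. After this correction 15 origin proteins were lower and 1 higher (median from -0.30 to -0.25), and 16 E2F targets lower and 2 higher (from -0.16 to -0.30). Under quantile normalization camera called the origin proteins, the E2F targets and the repair genes lower (adjusted p = 0.049, 0.025 and 0.043), but not with an estimated correlation (adjusted p = 0.13, 0.15 and 0.13). This list's median transcript was 4003 nt long, against 3244 nt for the origin proteins and 2914 nt for the E2F targets.

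Genes of G2 and mitosis moved both ways in SK-MEL-28, with 11 of 30 lower and 5 higher (median 0.00, camera adjusted p = 0.9), a balance that became 8 lower and 9 higher after rescaling by the median of ratios and 9 and 4 by quantile normalization. PTTG1, an inhibitor of sister chromatid separation, rose from 299 ± 9.68 to 564 ± 56.1 FPKM, and UBE2C from 82.7 ± 3.56 to 144 ± 4.94 FPKM. CCNB1, CCNB2 and CDC20 rose as well. KIF23, a motor of cell division, fell from 38.4 ± 2.53 to 20.9 ± 3.28 FPKM. MKI67, the proliferation marker, fell by 1.3 (adjusted p = 0.043; 0.063 by median of ratios), but this call was lost without any single SK-MEL-28 library except DMSO replicate 2. The adjusted p was 0.14 without DMSO replicate 1 or 3, and 0.084, 0.065 and 0.11 without XL413 replicate 1, 2 and 3. BAX rose by 0.64, a call lost without XL413 replicate 1 (0.53, adjusted p = 0.051). The median transcript of the mitotic list was 2838 nt long.

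Many genes of ribosomes and some of mitochondrial respiration rose. Of 30 cytosolic ribosomal proteins, 22 rose and 0 fell by limma (23 higher over the list alone, 24 at an unadjusted p under 0.05), led by RPS16, from 384 ± 55.7 to 848 ± 79.4 FPKM, and RPLP2, from 524 ± 5.30 to 1049 ± 132.5 FPKM. Of 26 oxidative phosphorylation genes, 12 rose and 0 fell (15 at an unadjusted p under 0.05), with NDUFB10, of complex I, at 0.93. COX4I1, of complex IV, rose by 1.15, a call lost without DMSO replicate 2 or 3 or XL413 replicate 1 or 2, at 1.04, 1.02, 1.02 and 0.84 (adjusted p 0.089 to 0.11). Of 9 replication-dependent histone genes 8 rose, with HIST1H4H at 2.20 and HIST1H4C at 2.15. Among 30 ribosome biogenesis and MYC targets 13 rose and 7 fell (14 and 7 over the list alone). PES1, of ribosome assembly, rose by 0.73, while CAD, of pyrimidine synthesis, and UTP20, of ribosomal RNA processing, fell by 1.06 and 0.87. The medians of the ribosomal, oxidative phosphorylation, histone and biogenesis lists were 0.56, 0.27, 1.10 and 0.20, with camera adjusted p = 3.3e-10, 0.00015, 7.6e-05 and 0.047. With an estimated correlation the adjusted p = 0.16, 0.16, 0.23 and 0.16, so none was called. Quantile normalization ended the calls of the ribosomal proteins (3 higher, 1 lower, median 0.08, adjusted p = 0.44), oxidative phosphorylation (4 higher, 2 lower, 0.10, 0.29) and ribosome biogenesis (10 higher, 8 lower, 0.04, 0.49), and the last was also lost without DMSO replicate 1 (0.053), XL413 replicate 1 (0.065) or XL413 replicate 2 (0.11). The biogenesis call ended with a pseudocount of 1 (camera adjusted p = 0.052) and with the replicate block (0.074) as well.

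**Figure D3:**
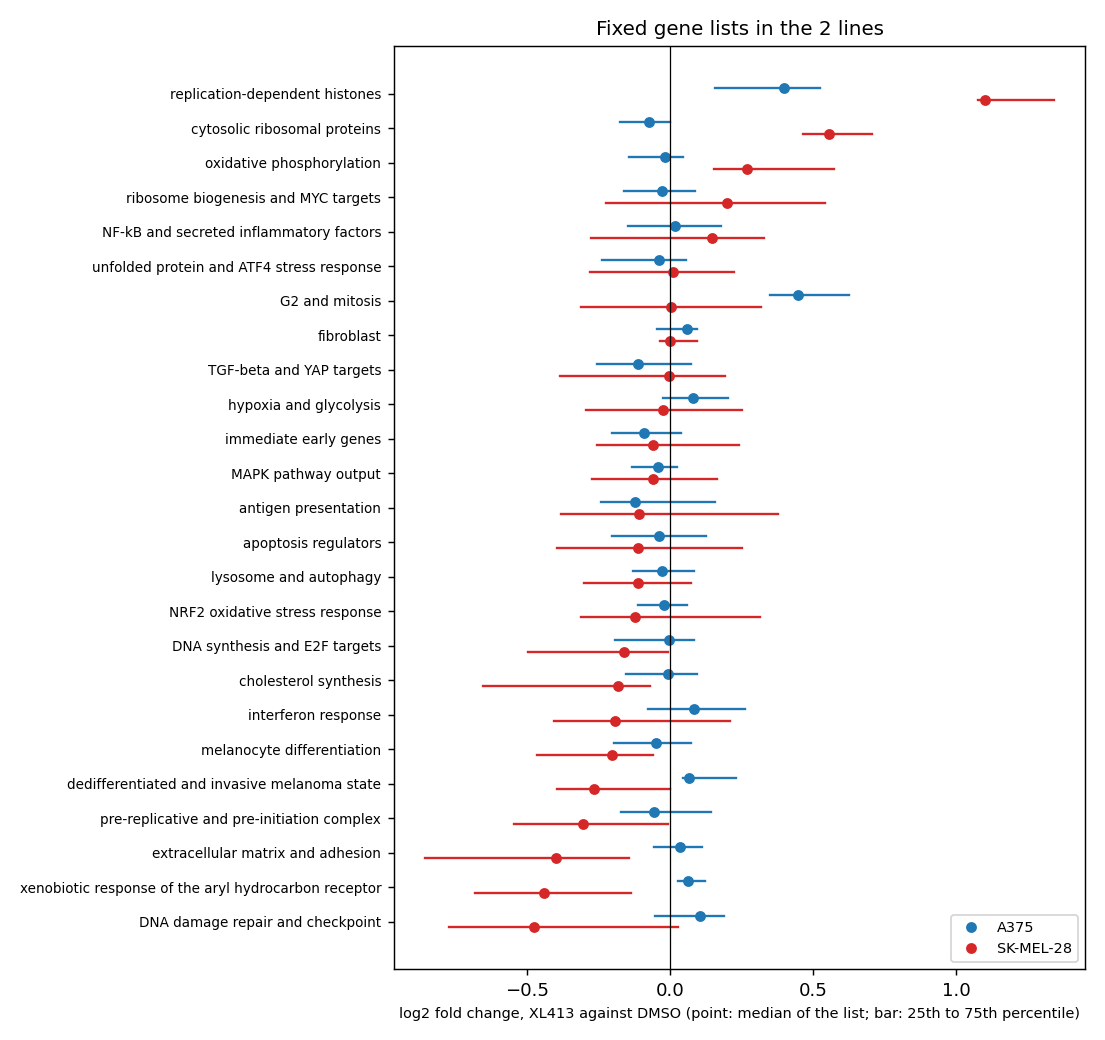
Log2 fold change, XL413 against DMSO (horizontal axis), of 25 gene lists in A375 and SK-MEL-28; points are the medians over the tested genes of a list, and bars span their 25th to 75th percentiles. The mitotic list lies at 0.45 in A375 and 0.00 in SK-MEL-28, where histones (1.10) and ribosomal proteins (0.56) lie highest.

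The lists that rose hold short transcripts, with medians of 789 nt for histones, 1036 nt for ribosomal proteins, 1512 nt for oxidative phosphorylation and 2383 nt for ribosome biogenesis. In the same comparison the log2 fold change fell with transcript length across 12156 protein-coding genes (Spearman's rho -0.55; 0.18 in A375; genes are not independent replicates). The median went from 0.39 in the shortest of 8 equal bins (1004 nt) to -0.58 in the longest (8220 nt). The largest rises included some RNAs that carry no poly(A) tail. SNORD3A, a small nucleolar RNA, was at 0.314, 1.42 and 0.668 FPKM with DMSO and at 13.8, 149.8 and 133.8 FPKM with XL413, and the splicing RNA RNU1-1 at 0.260, 1.39 and 0.239 and at 9.66, 71.2 and 66.4 FPKM. RNU1-3, another U1 gene, rose by 6.20 on the log2 scale, and RNA5SP202, a 5S ribosomal RNA pseudogene, was at 6.75, 59.4 and 77.9 FPKM with XL413, from 0, 1.52 and 0. Of 36 small nuclear RNA genes tested, 22 rose and 2 fell (median 3.17), but of 103 small nucleolar RNA genes 17 rose and 7 fell (median 0.29), and of 52 microRNA genes 10 rose and 5 fell (median -0.04). Genes near 0 elsewhere can pass the filter on low values through the SK-MEL-28 XL413 libraries alone, so these counts and medians may be partly set by it. After each library was corrected for its trend with length and GC content, a step chosen after seeing this trend, 9 ribosomal proteins were higher and 2 lower (median 0.16, camera adjusted p = 0.00023), 2 and 3 oxidative phosphorylation genes (median 0.07, adjusted p = 0.11), 8 and 9 ribosome biogenesis genes (median -0.02, adjusted p = 0.11), 3 and 0 histones (median 0.66, adjusted p = 0.00044) and 2 and 7 matrix genes (median -0.12, adjusted p = 0.88). With an estimated correlation neither of the lists still called held (adjusted p = 0.25 for both).

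**Figure D4:**
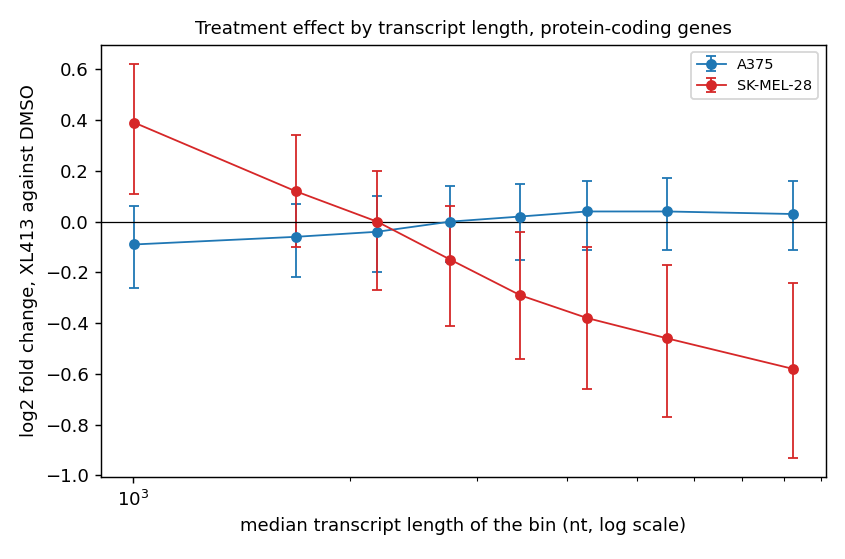
Median log2 fold change, XL413 against DMSO (vertical axis), of protein-coding genes in 8 bins of transcript length (horizontal axis, nt, log scale) in both lines; bars span the 25th to 75th percentiles of the bin. SK-MEL-28 goes from 0.39 to -0.58, and A375 stays between -0.09 and 0.04.

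**Figure D5:**
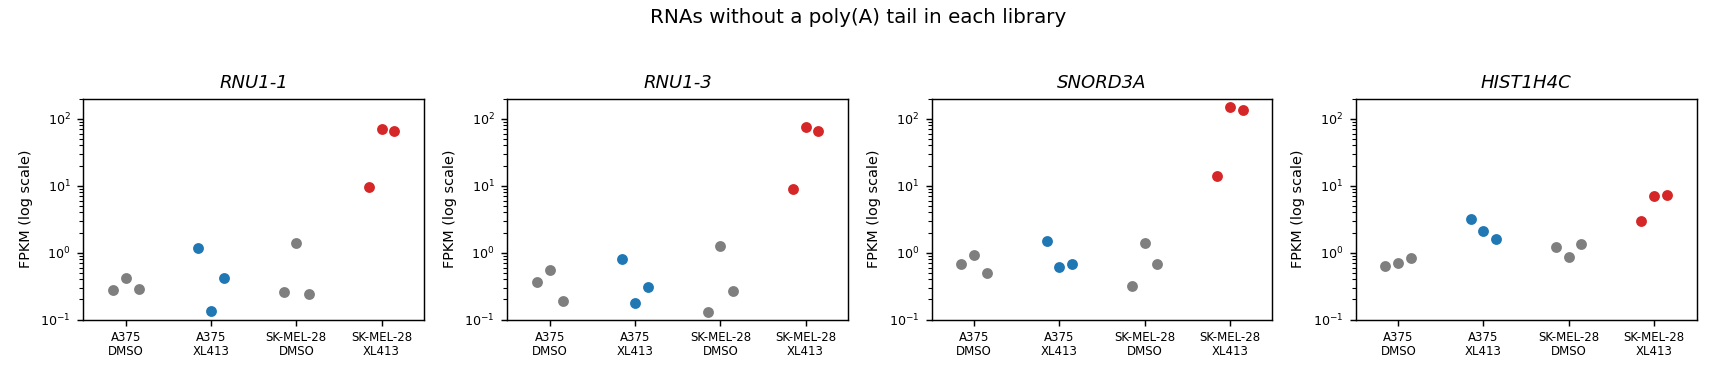
FPKM (vertical axes, log scale) of RNU1-1, RNU1-3, SNORD3A and the histone gene HIST1H4C in each library, by cell line and treatment; points are libraries. For RNU1-1, RNU1-3 and SNORD3A the SK-MEL-28 XL413 libraries lie highest, with replicate 1 below replicates 2 and 3, whereas for HIST1H4C replicate 1 lies below an A375 XL413 library.

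Metabolic and signalling genes changed in SK-MEL-28 as well. Of 25 cholesterol synthesis genes 11 fell, with SREBF2, their main transcription factor, from 70.4 ± 6.74 to 35.7 ± 2.76 FPKM, and LSS, which closes the sterol rings, at -1.12, while EBP and PMVK rose (camera adjusted p = 0.18). Of 7 aryl hydrocarbon receptor targets 5 fell, TIPARP by 2.39 beside AHRR, CYP1A1, ALDH1A3 and LAMA4 (camera adjusted p = 0.18). Under quantile normalization camera called the cholesterol and aryl hydrocarbon receptor lists lower (adjusted p = 0.021 and 0.049), and lysosome and autophagy as well (0.028), but none with an estimated correlation (adjusted p = 0.13, 0.36 and 0.13). Of 23 NRF2 response genes 7 fell, TXNRD1, a thioredoxin reductase, by 1.62, and TXN, PRDX1, FTL and TALDO1 rose (camera adjusted p = 0.97), although the median of ratios gave 5 lower and 5 higher and quantile normalization 5 and 0 (0.84 and 0.29). Interferon response genes moved both ways, 7 of 25 lower and 4 higher (camera adjusted p = 0.97), against 6 and 6 by median of ratios and 3 and 5 by quantile normalization. OAS3 and OAS2, which make the activator of RNase L, fell by 1.14 and 1.00, and IFI6, ISG15, BST2 and IFI35 rose, the first pair by 0.87 and 0.83. The call of OAS2 was lost without any DMSO replicate (adjusted p 0.058 to 0.076) or without XL413 replicate 2 (-0.61, 0.078). After the correction for length and GC content, the calls of BAX, BCL2A1, IFI6, ISG15, MKI67, COX4I1 and NDUFB10 ended, at log2 fold changes of 0.24, 0.12, 0.28, 0.13, -0.82, 0.58 and 0.26. Median transcripts were 2747 nt long for cholesterol synthesis, 4181 nt for aryl hydrocarbon receptor targets, 2391 nt for the NRF2 response and 2496 nt for the interferon response.

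Other lists in SK-MEL-28 split, with no camera call (adjusted p = 0.38 or higher). Of 25 NF-kB and secreted factors 6 rose and SERPINB2, TNFAIP3, PTGS2, LIF and NFKB1 fell. The median of ratios gave 9 higher and 4 lower, and quantile normalization 7 and 3. Of 30 stress response genes 6 rose, SDF2L1 by 0.65 (0.01 after the correction for length and GC content), and 6 fell, against 9 and 6 by median of ratios and 3 and 11 by quantile normalization. Apoptosis regulators fell in 6 of 29 and rose in 5 (XIAP, BAX, BCL2A1, BAD and BBC3), against 1 and 7 by median of ratios. MAPK output rose in 3 of 20 (DUSP5, IER3, EGR1) and fell in 4 (SPRY4, SPRED2, SPRED1, SPRY2), against 5 and 3 by median of ratios and 3 and 9 by quantile normalization. Immediate early genes rose in 4 of 24 (IER3, JUNB, BTG1, EGR1) and fell in 4 (NR4A1, NR4A2, JUN, ZFP36), against 6 and 2, and 4 and 0, in these settings. Hypoxia and glycolysis genes fell in 5 of 25 (ENO2, PFKFB3, VEGFA, PDK1, PFKP) and rose in 4 (ALDOC, ANKRD37, ALDOA, BNIP3), which became 4 and 8 by median of ratios and 6 and 3 by quantile normalization. TGF-beta and YAP targets rose in 4 of 21 (ID1, TGFB1, CTGF, PMEPA1) and fell in 4 (SKIL, CRIM1, AMOTL2, LATS2). Antigen presentation rose in 2 of 13 (PSMB10, HLA-DPB1) and fell in 3 (ERAP1, NLRC5, CANX), against 3 and 3, and 2 and 4. Of 12 tested markers of fibroblasts, epithelium, immune cells and endothelium, KRT18 rose and DSP and KDR fell, and limma called none of them in A375 (0 at an unadjusted p under 0.05).

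The steepest falls in SK-MEL-28 were genes listed at or near 0 with XL413. SENP3-EIF4A1, a read-through gene that shares exons with its neighbours, was at 11.3, 7.66 and 37.5 FPKM with DMSO and listed at 0 in the 3 XL413 libraries, as were NSF (7.09, 6.55 and 4.34 with DMSO) and the pseudogene TCAF1P1 (6.21, 5.50 and 6.64). PNRC2, of mRNA decay, was at 40.2, 42.6 and 41.8 FPKM and then 1.12, 0.809 and 1.06. AKAP2, which also shares exons, was at 6.78, 6.43 and 7.86 FPKM and then 0, 0 and 0.709, and EID1, a nuclear inhibitor of differentiation, at 83.2, 89.8 and 89.5 and then 2.87, 4.56 and 5.57. EID1 was not called without any one of the 6 SK-MEL-28 libraries (adjusted p 0.056 to 0.088), and in A375 it ranged from 3.02 to 117.8 FPKM within the DMSO group. A 0 in this table need not mean a silent gene, because 37 of 37 genes of the mitochondrial chromosome were listed at 0 in all 12 libraries.

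In SK-MEL-28, 7110 of 16205 genes passed the threshold (2462 higher, 4648 lower; 34.6% higher), 1389 of them with at least a 2-fold change (244 higher, 1145 lower), and groups did not overlap for 54.1% of genes, where chance gives 10%. Rescaling by the median of ratios moved the median of all genes from -0.11 to -0.002 and gave 6996 genes, 48.9% of them higher, so directions of small changes are relative to that shift. Of 12156 protein-coding genes tested alone 5602 passed (1608 higher, 3994 lower), and with the correction for length and GC content 4274 (891 higher, 3383 lower).

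The treatment effects differed between the lines for many of the same genes, the question being whether both respond alike. Genes of G2 and mitosis rose less or fell in SK-MEL-28 relative to A375 for 15 of 30, with 1 moving the other way and a median difference of -0.55. CDK1 was at 57.0 ± 4.46 and 56.9 ± 3.09 FPKM in SK-MEL-28, a difference of -0.89 from its rise in A375, and TOP2A at 75 ± 2.16 and 82.3 ± 6.96 FPKM (-0.75), while UBE2C rose in both (difference -0.05, adjusted p = 0.718). MITF stayed at 27.0 ± 1.2 and 27.9 ± 3.95 FPKM in A375 (difference -2.20, adjusted p = 6.7e-05), and ITGB3 at 164 ± 5.16 and 163 ± 11 FPKM (-1.72, adjusted p = 0.000283). Ribosomal proteins (17 of 30 higher, 0 lower and 20 at an unadjusted p under 0.05, median difference 0.69), oxidative phosphorylation (9 of 26, 0.44), histones (4 of 9, 0.87) and matrix genes (13 of 26 lower, 1 higher, -0.53) differed too. The camera adjusted p = 0.00016 for mitosis, 5.3e-08 for ribosomal proteins, 0.0021 for oxidative phosphorylation, 0.012 for histones and 0.0079 for matrix genes became an adjusted p = 0.21, 0.27, 0.21, 0.41 and 0.32 with an estimated correlation. Across 12156 protein-coding genes the difference itself fell with transcript length (Spearman's rho -0.52) and rose with GC content (0.32). Ribosomal, oxidative phosphorylation and histone genes have short transcripts and matrix genes long ones. The differences of these lists were not tested after the correction for length and GC content.

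Of the genes passing the threshold in both lines, 19 were higher in both (14.7 by chance) and 23 lower in both (46.2 by chance). These chance counts, and those below, take no account of library trends that run in opposite directions in the lines. Spearman's rho was 0.18 in A375 and -0.55 in SK-MEL-28 with transcript length, and -0.43 and 0.19 with GC content. How far such trends set the counts was not tested. LSM5 rose by 2.00 in SK-MEL-28, the long noncoding RNA AC112191.2 by 0.75 and 1.19 in A375 and SK-MEL-28, SNAPIN, a protein of vesicle fusion, by 0.67 and 0.76, and LRMDA by 0.61 in SK-MEL-28. Both lines lowered CCNE2, ATG16L2 (-1.52 in SK-MEL-28), EMILIN2 (-0.67), CSAD (-0.95) and LIMD1, a LIM-domain protein (-0.60 in A375 and -0.71 in SK-MEL-28). A further 42 genes rose in A375 and fell in SK-MEL-28 (27.8 by chance), MEX3C among them with -0.91 in SK-MEL-28, and 65 fell in A375 and rose in SK-MEL-28 (24.5 by chance), such as the noncoding genes AL390726.5 (-2.77 and 2.24), AC002044.1 (-2.21 and 1.5), AC103810.3 (-1.80 and 1.04) and AL022718.1 (-0.88 and 1.19). The A375 calls of AC112191.2, SNAPIN, LIMD1 and these 4 noncoding genes were lost without A375 DMSO replicate 1, 2 or 3 (adjusted p 0.054 to 0.16). All but AC112191.2 were also lost without A375 XL413 replicate 1 or 3 (0.051 to 0.14), and SNAPIN, AL390726.5, AC103810.3 and AL022718.1 without replicate 2 (0.072 to 0.15). LIMD1 and AL022718.1 lost theirs by the median of ratios (0.053, 0.054), and AC103810.3 with a pseudocount of 1 (-0.86, 0.055). In SK-MEL-28 the call of LRMDA was lost without DMSO replicate 1 or 3 (0.061, 0.078) or XL413 replicate 1 or 3 (0.056, 0.071). That of AC103810.3 was lost without DMSO replicate 1 or 2 (0.055, 0.087) or XL413 replicate 1 or 3 (0.075, 0.085), and that of AC002044.1 without XL413 replicate 1 (0.056). The correction for length and GC content ended the SK-MEL-28 calls of LRMDA, SNAPIN and LIMD1, at 0.10, 0.26 and -0.25, and the A375 calls of SNAPIN and LIMD1 (adjusted p = 0.074 and 0.05), whose fold changes there did not shrink (0.73 and -0.61).

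Over all 16205 genes the log2 fold changes of the lines were weakly opposed (Pearson's r -0.115, Spearman's rho -0.203, across genes, which are not independent replicates). Among 12156 protein-coding genes Spearman's rho was -0.213, and -0.121 after the correction for length and GC content. A test of the difference itself called 5580 genes (2219 higher in SK-MEL-28 relative to A375, 3361 lower; 1729 with at least a 2-fold difference). The largest were genes with values at 0. NSF was listed at 0 in A375 DMSO replicates 2 and 3 and in each SK-MEL-28 XL413 library. FRG1, an RNA-processing protein, was at 21.0, 19.9 and 20.6 FPKM in A375 with DMSO, 0 in the 3 with XL413, and 36.1, 0 and 24.9 FPKM in SK-MEL-28 with XL413.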

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

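The tests of length and GC content and of further genes for the mitotic list, and of histones for the length trend, were chosen after those results were seen.

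The treatment effect differed between the lines for 5580 genes by the test of the difference. Of 100 splits of the libraries within both lines (of 200 possible), 1, the real one, gave as many, and the highest other gave 4581. Splits that keep the SK-MEL-28 treatment groups intact call many genes by that structure alone. The real split thus gave the most calls of those drawn. Most splits mix both lines at once, so the set asks whether treatment had any effect, not whether the lines differ. Chance is therefore not excluded for the difference between the lines, and the part due to A375 is not given by the count. For the other counts 10 splits of 6 libraries are too few to give a share under 0.05: in A375 the real split called 258 genes and the highest other 11 (1 of 10 as large), in SK-MEL-28 7110 and 7 (1 of 10). For the lists called, the real and highest other numbers were 1 and 2 in A375 (10 of 10 splits as large) and 5 and 4 in SK-MEL-28 (1 of 10). Every other split in A375 thus called a list too, so the number of lists called there does not set the real grouping apart. Which lists the other splits called was not examined.

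Medians of 5 lists differed between the lines (SK-MEL-28 minus A375): G2 and mitosis by -0.55, replication-dependent histones by 0.87, extracellular matrix and adhesion by -0.53, cytosolic ribosomal proteins by 0.69 and oxidative phosphorylation by 0.44. None of these was called with an estimated correlation (adjusted p 0.21 to 0.41). The difference also fell with transcript length across protein-coding genes (Spearman's rho -0.52), and these lists were not tested for it after the correction.

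Of 86 named genes, 67 differed between the lines; each value is the log2 fold change in SK-MEL-28 minus that in A375. In replication and DNA synthesis these were CDC7 -0.56, CDC45 0.47, DBF4B -1.37, TOPBP1 -1.07, RECQL4 1.00, CCNE2 -1.21, POLD3 -1.03 and POLA1 -0.89. Mitotic genes were CDK1 -0.89, TOP2A -0.75, HMMR -1.16, PTTG1 0.51 and KIF23 -1.31. In the damage response and cell death they were ATM -1.93, XRCC2 -1.59, BRCA2 -1.70, POLH -0.97, PPM1D -0.66, RRM2B -1.32, BAX 1.33, BIRC2 -0.37 and BCL2A1 0.84. Melanocyte and matrix genes were MITF -2.20, GPNMB -0.78, TNC -1.66, ITGB3 -1.72, COL4A2 -1.69, EMILIN2 0.81 and SPARC -0.61. Interferon, stress and metabolic genes were ISG15 1.62, OAS3 -1.23, OAS2 -1.53, IFI6 0.80, SDF2L1 1.12, CEBPB 0.55, JUND 0.63, P4HA1 -0.39, SREBF2 -0.95, TXNRD1 -1.58 and TIPARP -2.45. Ribosomal and mitochondrial genes were CAD -1.12, UTP20 -0.82, PES1 0.98, RPS16 1.36, RPLP2 1.07 and NDUFB10 0.73. Small RNAs without a poly(A) tail were SNORD3A 6.08, RNU1-3 6.12 and RNU1-1 5.64, and the histone gene HIST1H4H was at 1.67. Single genes outside the lists were MEX3C -2.31, LSM5 0.97, SPIN1 -1.15, PYROXD1 -1.66, FAM173A 1.78, AL390726.5 5.01, AC002044.1 3.71, AC103810.3 2.83 and AL022718.1 2.07. The differences of PNRC2, -6.81, and EID1, -6.20, rest in part on values that jumped within an A375 group. With DMSO in A375, PNRC2 was at 2.63, 43.1 and 43.4 FPKM and EID1 at 117.8, 4.79 and 3.02 FPKM. Fitted differences of genes listed at 0 in some libraries rest on the added 0.1 and are no folds: CT45A3 -8.09, NSF -9.76, FRG1 9.21, RNA5SP202 7.22, TCAF1P1 -6.05 and AKAP2 -5.22.

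The mitotic list rose in A375 with a median of 0.45. A trend with transcript length and GC content is argued against as the whole cause, since the median was 0.41 after each library was corrected and the list was still called. Bias by expression level, length and GC content together is argued against too: of 10000 random lists matched on these, the highest median was 0.219. More cells in G2 or mitosis in the treated cultures remains a hypothesis that the design allows, and 34 further mitotic genes outside the list had a median of 0.37 in A375, which is consistent with it. Cell counts or cycle profiles are not given in the sources used here, so a change per cell stays open.

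In SK-MEL-28 short transcripts rose and long ones fell with XL413. A lower capture of polyadenylated RNA in the treated libraries may contribute. The histone median was 1.10 against 0 to 0.67 for the middle 95% of lists matched on length. Of the 9 histones behind it, 7 passed the filter on low values in the other 9 libraries, so this median may be partly set by the filter. Without a filter 18 of 18 histone entries were higher (median 1.3). Whether these histone transcripts lacked a poly(A) tail was not tested. DMSO replicate 2 was the control with the highest median of 27 entries for RNAs without a poly(A) tail, unfiltered (1.28 FPKM against 0.260 and 0.239). It also leaned to short transcripts (rho -0.27 against 0.06 and 0.18). Yet the length trend was as strong in XL413 replicate 1 (rho -0.50) as in replicates 2 and 3 (-0.51). The median of the 27 entries was 8.02 FPKM in XL413 replicate 1 against 45.5 and 26.0. RNA fragmentation that shortens the captured part of long transcripts stays possible. The fold change fell with coding length at fixed 3′ UTR length (partial rho -0.51) and with 3′ UTR length at fixed coding length (-0.34). Both are parts of transcript length, so any cause that acts on total length would give these signs. The test therefore cannot tell fragmentation from such causes. Lower transcription of genes that span long stretches of the genome cannot be told apart, as the partial rho with genomic span at fixed transcript length, -0.17, lay between the bounds set beforehand. A change in RNA make-up by the drug itself stays open and untested, because capture and treatment coincide in these 3 libraries.

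Values of some genes jumped between 0 and a high level among libraries of one group, as for NSF and FRG1, and 539 of 16205 genes ranged over 8-fold within at least 1 group. Exons shared with another gene on the same strand may account for part of this. This was compared only among genes with a mean of at least 5 FPKM in a group, with the 8-fold range in such a group. Of these, 3.54% of 1866 genes with such an overlap were unstable, against 0.78% of 9498 others, a ratio of 4.54. Most unstable genes at this level had no such overlap (74 against 66), so the rest is open. No biological explanation was tested.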

How the results depend on the processing

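Added after seeing the data were protein-coding genes alone, the correction for length and GC content, the removal of genes ranging over 8-fold within a group, and quantile normalization for the lists. Unless the construction shows it, the cause of a change was not tested. The A375 count of 258 became 415 with a pseudocount of 1, 421 after quantile normalization, 8 with a replicate block (adjusted p = 0.051 for CDK1 and UBE2C, 0.056 for TOP2A, 0.076 for SPIN1, 0.09 for FAM173A), 899 with weights per library, 28 with a 2-fold minimum (a stricter rule), 36 with the line alone (fewer libraries for the spread), 175 for protein-coding genes alone, 85 for these after the length and GC correction, and 43 to 384 leaving out a library (fewer samples). Replicate numbers pair no samples here: same-number correlations were -0.05 to 0.01, so the block uses up degrees of freedom. With it CDC7 in SK-MEL-28 was at adjusted p = 0.06. In SK-MEL-28, 7110 became 1389 with the 2-fold minimum, 5602 for protein-coding genes alone and 4274 for these after the correction, and stayed at 5848 to 7060 without any single library; the difference of 5580 became 1729, 4397 and 2752 in these settings. All results after the correction are for protein-coding genes. The lists called in A375 went from 1 to 2 with fry, the block, quantile normalization, the correction or leaving out a library (1 to 2); those in SK-MEL-28 from 5 to 0 with an estimated correlation, 18 with fry, which does not compare a list with other genes, 9 (1 higher, 8 lower) after quantile normalization and 2 after the correction. The correlation between the lines, -0.115, was -0.175 and -0.065 with a pseudocount of 1 and 0.01, -0.06 without a filter, -0.174 with the stricter filter, -0.139 for protein-coding genes, -0.084 after the correction, -0.145 without unstable genes, and -0.141 to -0.072 leaving out a library. Reversed were CDC7 in A375, uncalled at 0.08, to -0.05 after the correction and -0.01 without A375 XL413 replicate 2 (0.19 without replicate 1), and the ribosome biogenesis list in SK-MEL-28, to -0.02 after the correction. Named genes were recomputed only with a pseudocount of 1, the median of ratios, the replicate block, the correction, and without each library of the same line. Of these 1044 alternatives 823 kept direction and side of the threshold, 218 kept direction but lost the call, 1 gained one and 2 reversed. Of 101 called values 62 stayed called in each of these settings that was planned beforehand. When a library of the same line was left out, 34 lost the call. The other planned settings were not run for named genes. A count model was not run, since whole reads could not be recovered. Small changes can be missed: of planted 1.5-fold changes 25.4% and 34.3% were recovered in simulations for A375 and SK-MEL-28. Few genes were changed in these (67 by 1.5-fold), which makes the adjusted threshold stricter than with 7110 genes called. The recovery in the real SK-MEL-28 comparison is therefore not given by them.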

Other observations

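The lists of further mitotic genes and of RNAs without a poly(A) tail were chosen after the results were seen.

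In SK-MEL-28 the 34 further mitotic genes had 17 lower and 2 higher with a median of -0.40, where A375 had 10 higher by limma. For the list in SK-MEL-28 the camera p was 0.023, and 0.14 with an estimated correlation. The difference between the lines had a median of -0.76, with a camera p of 2.6e-07 and of 0.0059 with an estimated correlation. Of 26 listed RNAs without a poly(A) tail 18 passed the filter on low values, but only 9 did so in the 9 libraries other than SK-MEL-28 with XL413, so a test of those 18 would be partly set by the filter. Without a filter and untested, 24 of 27 table entries of these RNAs had a higher mean with XL413 in SK-MEL-28 and 3 were at 0 in that line, with a median log2 fold change of 4.07; in A375 11 were higher and 12 lower. Of 18 table entries of replication-dependent histones 18 were higher in SK-MEL-28 without a filter (median 1.3), and 9 higher and 9 lower in A375 (0.03).

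By gene type, A375 lowered 12 of 704 long intergenic RNA genes by limma, and SK-MEL-28 raised 478 and lowered 290 of 1411 processed pseudogenes. The sum of FPKM was 508374, 520281 and 497174 in the SK-MEL-28 XL413 libraries and 430085, 438702 and 423940 in the DMSO libraries, while the A375 libraries lay between 446089 and 460524.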
